A study of Mus musculus with 16 samples.

How the data were processed

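Nucleus pulposus tissue of mice was profiled on 16 Affymetrix arrays, 4 for each combination of genotype (floxed control or arrays labelled HIF-2α cKO) and age (6 or 14 months). Per the labels' protocols, total RNA was labelled with biotin by the standard Affymetrix procedure. The deposited table holds 1 value per probe set and array on the log2 scale, as read from the values themselves (2.46 to 19.93, none missing). The software, background correction and summarizing method are not given in the sources used here. Column means lay within a narrow range, from 7.02 to 7.11 (log2), while medians and interquartile ranges differed. The values were used as deposited, without further normalization. No other per-array columns were present (0). Signal over background is not given, so a low value cannot be told from absence of transcript, and the floor of the values limits how low a dim gene can be seen, so folds from or to such values are not exact. The median of 1414 olfactory and vomeronasal receptor probe sets, a level chosen after the data had been seen, marks where that applies to the largest named changes.

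Probe sets were named through the platform annotation supplied with the data. Of 22206 probe sets 19572 had 1 gene symbol, 0 had several and 2634 had none. All 19572 symbols were matched by Entrez identifier to a gene table, which gave 19505 distinct symbols. Where a gene had several probe sets, counts of calls refer to probe sets. Gene lists used the probe set with the highest mean over all arrays. The genome build of the array design is not stated, so no coordinates are printed. Multi-copy families such as Sly and Btbd35f have near-identical copies that share probes, and their members cannot be told apart.

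Groups were taken from the titles and characteristics of the samples. A linear model with 4 group means was fitted to all 16 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that the groups share 1 estimate of the spread per probe set. The contrasts were cKO minus control at each age, 14 minus 6 months in each genotype, and the difference between the genotype effects at the 2 ages. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all 22206 probe sets. SE is the moderated standard error of limma, and mean ± SD is over the 4 arrays of a group. Gene lists were fixed from textbook knowledge before the data were examined. They covered HIF and hypoxia genes, metabolism, disc matrix, stress, inflammation and markers of other cells that a dissected disc could hold. Among them, the clock, the immediate early and heat shock, and the ribosomal protein lists were fixed as checks, apart from the study lists. Of 32 lists 31 were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives.

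Genes named in the text follow a rule written before the data were examined. It takes Epas1 and Hif1a, the 8 largest rises and 8 largest falls among called probe sets of each comparison, and, of lists that were called or held a called gene, up to 4 members of smallest p. Of the glycolysis, hypoxia, catabolic, collagen, nucleus pulposus and cartilage lists it takes the 3 members of smallest p in the genotype comparisons. Where a direction held fewer than 3 calls, the 5 probe sets of smallest p were taken. Further members of a fixed list could be named to say what the list did. Predicted genes and olfactory or vomeronasal receptors were counted but not named. Sex was read from the mean of the 3 Y-linked genes Eif2s3y, Kdm5d and Uty, which lay between 3.30 and 4.12 on 9 arrays and between 7.97 and 9.56 on 7, on either side of a threshold of 6.

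Alternatives fixed before the data were examined were quantile normalization, shifting arrays to one median, leaving out dim probe sets (12421 of 22206 lay above the array median on at least 4 arrays), 1 probe set per gene, array weights, a trended and robust prior, only the arrays of the groups compared, other thresholds, the replicate number as a block, sex as a covariate, and leaving out each array in turn. Arrays of 1 sex only, sex as a covariate for the correlations between comparisons, and the omission of 2 arrays with high neutrophil markers were added after the data had been seen. The main limma fit and camera at its preset correlation were tested on simulated data, and the alternatives were not. Noise was drawn independently for each probe set, without correlation between genes, sex imbalance or differences in spread between arrays. At 6 months the limma fit recovered 35 of 100 genes changed by 1 and 96 of 100 changed by 2 (log2), with 15 false calls. For age it recovered 36 and 94 of 100 in controls and 40 and 94 in cKO. For the genotype by age term it recovered 10 and 67. No recovered gene had the wrong sign (0). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.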

Results

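Gene expression was measured on Affymetrix microarrays in the nucleus pulposus, the gel-like core of the intervertebral disc, of 2 kinds of mice. Control mice carried a floxed gene for HIF-2α, the hypoxia-inducible transcription factor encoded by Epas1, and the others were labelled as conditional knockouts (cKO) of it. The 16 arrays formed 4 groups of 4 arrays each: control and cKO at 6 months of age, and control and cKO at 14 months. Each array gave a log2 value for 22206 probe sets, between 2.46 and 19.93, and 19572 of these carried 1 gene symbol, for 19505 distinct genes. The comparisons ask how deletion of HIF-2α changed expression at each age, how expression changed with age in each genotype, and whether the effect of genotype depended on age. The design text gives 4 mice a group, but whether each array holds tissue of 1 mouse is not stated. The p-values of limma for single genes thus measure the spread between these arrays. With 4 arrays a group, their number limits the precision of every value.

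The largest component of variance between arrays separated the ages. The first principal component held 46.6% of the variance and separated every 6-month array (-81.2 to -18.4) from every 14-month array (22.5 to 89.0). The second held 16.6% and separated arrays by the sex of the mice, which was read from the Y-linked genes Eif2s3y, Kdm5d and Uty, since the labels do not give it. Of 4 arrays each, 0 were male among 6-month controls, 3 among 6-month cKO, 1 among 14-month controls and 3 among 14-month cKO. Sex and genotype thus overlapped at both ages, most at 6 months. Pearson correlations between arrays over all probe sets ran from 0.897 to 0.987, and from 0.942 to 0.987 within a group. The interquartile range of an array's values was 3.30 ± 0.15 in 6-month controls, 3.56 ± 0.17 in 6-month cKO, 3.85 ± 0.21 in 14-month controls and 3.95 ± 0.087 in 14-month cKO (log2, SD, n = 4). In each group the array with the narrowest range also had the lowest value on the first component. Examples are 6-month cKO array 2 (range 3.34, component -73.7) and 14-month control array 1 (3.64 and 22.5). The first component thus went with the spread of values as well as with age, and does not single out age.

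**Figure D1:**
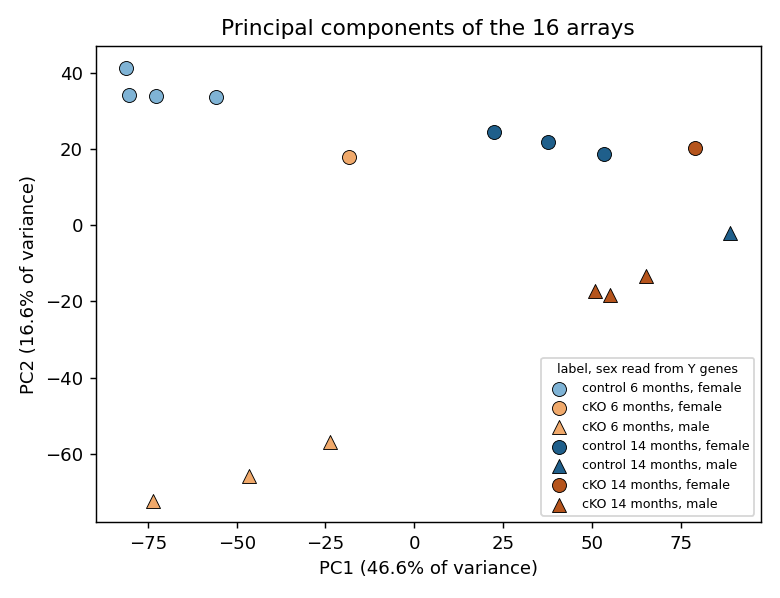
First against second principal component of the 16 arrays over all probe sets, coloured by group, with circles for arrays read as female and triangles for arrays read as male. The first component (46.6% of the variance) separates the ages, and the second (16.6%) the sexes, more widely at 6 than at 14 months.

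Epas1, the targeted gene, was not lower on arrays labelled cKO. Its mean was 9.51 ± 1.28 in controls and 10.38 ± 0.41 in cKO at 6 months, and 10.69 ± 0.91 in controls and 12.01 ± 0.36 in cKO at 14 months (log2, SD, n = 4). The differences of 0.87 (SE 0.50, adjusted p = 0.35) and 1.32 (SE 0.50, adjusted p = 1) did not pass the limma test. The 6-month controls fell into pairs, with Epas1 at 8.34 and 8.46 on arrays 1 and 3 and at 10.63 and 10.6 on arrays 2 and 4. The latter lay level with the 6-month cKO arrays (9.79 to 10.68). Among arrays labelled cKO, Epas1 was 3.1-fold higher at 14 than at 6 months (log2 change 1.63, SE 0.50, adjusted p = 0.025), a call that quantile normalization ended (adjusted p = 0.06). Where the Epas1 probes lie relative to the deleted part of the gene is not given in the sources used here, so its value does not check the labels. Groups are therefore named as the arrays are labelled, and each direction by genotype rests on those labels. Hif1a, which encodes the related HIF-1α, had means of 13.68 ± 0.28, 14.08 ± 0.69, 14.14 ± 0.27 and 14.30 ± 0.32 in the same order of groups, and passed no comparison.

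**Figure D2:**
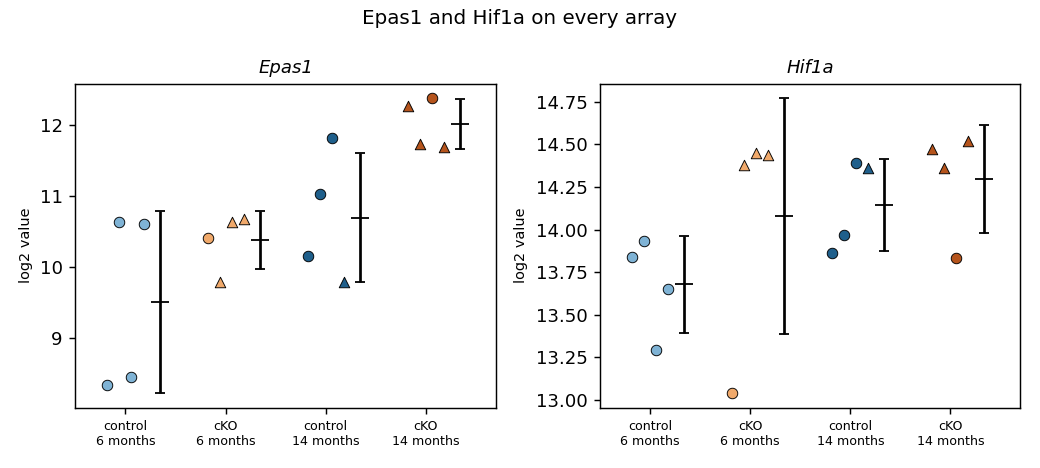
Log2 values of Epas1 and Hif1a on each of the 16 arrays by group, with circles for arrays read as female, triangles for arrays read as male, and bars for the mean and SD of 4 arrays. Epas1 means run from 9.51 in 6-month controls to 12.01 in 14-month arrays labelled cKO.

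At 6 months, arrays labelled cKO had more transcript of immediate early, heat shock and glycolytic genes than controls. Pim1, a serine/threonine kinase, was 27.5-fold higher (log2 change 4.78, SE 0.61, adjusted p = 0.00046, n = 4), and Emp1, a membrane protein of epithelia, 28.1-fold (4.81, SE 0.75, adjusted p = 0.0026). The immediate early nuclear receptor Nr4a1 rose from 6.31 ± 0.82 to 10.23 ± 0.74 (adjusted p = 2.6e-05), the transcriptional co-regulator Ifrd1 from 5.27 ± 0.42 to 9.09 ± 0.51 (adjusted p = 1.9e-05) and Errfi1, a feedback inhibitor of the EGF receptor, from 9.04 ± 0.45 to 12.91 ± 1.12 (adjusted p = 0.00023). The ephrin receptor Epha2 was 16.5-fold higher (4.05, SE 0.77). Among the genes that fell, the amino acid transporter Slc7a8 was 10.4-fold lower (-3.38, SE 0.59, adjusted p = 0.0052) and the clock-controlled transcription factor Dbp 9.99-fold lower (-3.32, SE 0.45, adjusted p = 0.00073). The adhesion receptor Adgrg6 fell from 9.11 ± 0.17 to 6.76 ± 0.28 and Ndnf, a secreted neurotrophic factor, from 12.97 ± 0.48 to 10.75 ± 0.50. Cdh4, a cadherin, fell by 2.51 (SE 0.62), the homeobox gene Dlx5 by 2.48 (SE 0.53), Mid1, an X-linked ubiquitin ligase, by 2.64 (SE 0.74), and AI506816 was lower too (-2.11, SE 0.29). Sly, a multi-copy gene of the Y chromosome, was among the largest rises with 2 probe sets (4.24, SE 0.97, and 3.98, SE 0.89). Epha2 and Ifrd1 in controls (5.20 and 5.27) and Cdh4 in cKO (4.89) lay below the median of olfactory and vomeronasal receptor probe sets on the same arrays (5.45 and 5.23), so their folds depend on the floor of the values.

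Of 18 measured genes of glycolysis and glucose uptake, 9 rose and 0 fell (15 rose when adjusted over the list alone), with a median change of 0.88 (log2). They included the glucose transporters Slc2a1 (1.32, SE 0.17, adjusted p = 0.00046) and Slc2a3 (1.81, SE 0.41), hexokinase 2 (Hk2, 2.69, SE 0.35, adjusted p = 0.00058) and Pdk1, which restrains pyruvate entry into the citric acid cycle (1.21, SE 0.22). Of 20 other genes of the hypoxia response, 8 rose (9 rose and 1 fell adjusted over the list alone). Bnip3, a mitophagy receptor, rose by 1.95 (SE 0.26), Higd1a by 1.55 (SE 0.30), and the collagen prolyl hydroxylases P4ha2 and P4ha1 by 1.32 (SE 0.29) and 1.02 (SE 0.28). The median deviation of these hypoxia genes from their means over all arrays was -1.16 on control arrays 1 and 3. It was -0.22 and -0.47 on control arrays 2 and 4, within the range of the cKO arrays or near it (-0.56 to 0.16). Of 17 immediate early and heat shock genes, 10 rose and 0 fell (12 adjusted over the list alone), with a median of 1.58. Examples are the transcription factors Atf3 (3.71, SE 0.49) and Egr1 (2.87, SE 0.77), the phosphatase Dusp1 (3.75, SE 0.80) and the chaperone Hspa1a (2.28, SE 0.24). The immediate early and heat shock list was fixed as a check, and it varied within groups. Its median deviation from the means over all arrays was -0.98 and -1.2 on control arrays 1 and 3. It was 0.17 and 0.22 on control arrays 2 and 4, and 0.66 to 2 in cKO. What moved these genes was not tested. Of 14 genes of endoplasmic reticulum (ER) stress, 3 rose (5 adjusted over the list alone): Xbp1 (1.16, SE 0.27), Atf4 (1.66, SE 0.39) and Dnajb9 (0.92, SE 0.22).

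Limma's camera test called 9 of the 31 lists at 6 months, each shifted up against all other genes. Glycolysis, immediate early and heat shock genes and ER stress held with an estimated correlation between genes (adjusted p = 0.0251, 0.0251 and 0.0387). The other hypoxia genes did not (adjusted p = 1.03e-06 with the preset correlation, and 0.11 with an estimated correlation). The same was true of oxidative phosphorylation, where 2 of 22 genes rose (Ndufa4 and Uqcrfs1; 3 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Of 13 cytosolic ribosomal protein genes 6 rose, Rpl23 by 1.03 (SE 0.23) among them (9 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation). Of 16 autophagy genes Bnip3 alone passed, over all genes and adjusted over the list alone, where 1 rose (adjusted p = 0.181 with an estimated correlation). Of 10 HIF pathway genes 2 rose, Egln1, the main oxygen-sensing prolyl hydroxylase (1.43, SE 0.19), and Vhl (0.77, SE 0.20), the same count adjusted over the list alone, 2 (adjusted p = 0.162 with an estimated correlation).

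Few genes of the disc matrix lists passed at 6 months. Of 27 genes of collagens I, III, V and VI and fibrosis, 2 rose, Tgfb2 (1.71, SE 0.36, adjusted p = 0.015) and Col6a1 (0.92, SE 0.24, adjusted p = 0.035, and 0.14 after quantile normalization), and 25 did not pass (3 rose adjusted over the list alone). Of 23 cartilage matrix genes 0 passed, over all genes or adjusted over the list alone, and Col2a1, the main cartilage collagen, was at 8.67 ± 0.13 in controls and 7.84 ± 0.36 in cKO (adjusted p = 0.11). Of 16 nucleus pulposus and notochord markers 2 rose, the keratin Krt18 (1.76, SE 0.35) and Slc2a1 (4 rose adjusted over the list alone). Of 13 cartilage catabolic genes linked to HIF-2 in other work, 1 rose, Nampt, an enzyme of NAD synthesis (1.46, SE 0.27), also 1 adjusted over the list alone, and Mmp3, a matrix protease, was at 5.23 ± 0.57 and 4.64 ± 0.11 (adjusted p = 0.17). Camera called none of these 4 lists (adjusted p = 0.113, 0.113, 0.167 and 0.113). Single genes of other lists passed: the protease Ctsl (1.85, SE 0.39), the cell cycle inhibitor Cdkn1a (2.44, SE 0.45), the chemokine Cxcl2 (1.15, SE 0.31), Nfkbia (1.33, SE 0.38) and the interferon regulator Irf7 (2.28, SE 0.48) rose. Of 16 clock genes 4 rose (Arntl, Per1, Npas2 and Cry2) and 2 fell (Dbp and Per3), and the list as a whole was not shifted (5 rose and 3 fell adjusted over the list alone).

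Markers of other cells also differed at 6 months. Neutrophil and marrow myeloid markers lay a median of 1.90 and 2.27 above their means over all arrays on cKO arrays 3 and 4, and within -0.60 to 0.54 on the other 6-month arrays. Camera called this list up (adjusted p = 0.011), though 0 of its 14 genes passed, over all genes or adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.448 with an estimated correlation). Without those arrays the median change was -0.39. Of 11 lymphocyte markers, Cd3e fell (-1.09, SE 0.26). Markers of macrophages, erythroid cells, endothelium, muscle, nerve, fat, osteoclasts and annulus or tendon cells had 0 genes past the test.

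In all, limma called 1035 probe sets at 6 months, 766 higher and 269 lower in cKO, at an adjusted p under 0.05 (569 and 211 distinct named genes), of which 743 differed over 2-fold. After quantile normalization the split was 679 higher and 420 lower. The calls of P4ha1 (adjusted p = 0.1), Egr1 (0.057), Dnajb9 (0.076), Nfkbia (0.065) and Cry2 (0.11) were lost there, beside that of Col6a1. Of the calls, 166 were Y-linked, 164 of them higher, where 0 of 4 control arrays and 3 of 4 cKO arrays were male. With sex as a covariate 61 probe sets passed. The median change of the 869 calls off the Y chromosome went from 1.15 to 1.02, while its median SE went from 0.26 to 0.32 and 60 of them stayed called. The covariate is a single term over both ages, so it does not fully remove a sex effect that differs between the ages. The Y-linked calls, which go with sex, kept a median change of 1.81 with it, against 4.09 without. A kept call is thus not shown to be free of sex. With this covariate, 20 of 57 named results kept their call: Pim1 (adjusted p = 0.0088), Nr4a1 (0.00084), Ifrd1 (0.00075), Errfi1 (0.0067), Hk2 (0.018), Slc2a1 (0.016), Bnip3 (0.0068), Atf3 (0.018), Hspa1a (0.0031), Egln1 (0.015), Dbp (0.00075), Slc7a8 (0.023), Adgrg6 (0.013), Ndnf (0.0085), AI506816 (0.032), Pdk1 (0.018), Per3 (0.0086), Arntl (0.013), Npas2 (0.034) and Hspa1b (0.028). Emp1 (0.066), Epha2 (0.18), Mid1 (0.32), Cdh4 (0.34), Dlx5 (0.24) and both Sly probe sets did not. Nor did Ctsl (0.24), Cdkn1a (0.16), Cxcl2 (0.38), Nfkbia (0.23), Irf7 (0.21), Tgfb2 (0.15), Col6a1 (0.24), Krt18 (0.096), Nampt (0.088), Vhl (0.23), Higd1a (0.15), P4ha2 (0.18), Rpl23 (0.21), Cd3e (0.13), Slc2a3 (0.21), P4ha1 (0.27), Egr1 (0.17), Dusp1 (0.077), Ndufa4 (0.13), Uqcrfs1 (0.23), Per1 (0.23), Cry2 (0.41), or the ER stress genes Xbp1 (0.21), Atf4 (0.21) and Dnajb9 (0.19). Without cKO arrays 3 and 4, 92 probe sets passed, while the median change of the 1035 calls, signed by direction, went from 1.22 to 1.17 and its median SE from 0.281 to 0.342. This fit and the one with the covariate use arrays that selected the calls, so a kept median change is no independent check. Leaving out 1 array gave 508, 288 and 535 calls without control arrays 1, 3 and 4, and 382 and 314 without cKO arrays 3 and 4.

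At 14 months, no gene differed between genotypes past the test. Limma called 0 of 22206 probe sets (smallest adjusted p = 0.58), and 795 had an unadjusted p under 0.05, where chance alone gives 1110. The values with the smallest p are given here as differences that did not pass. Igfbp5, an insulin-like growth factor binding protein, was at 6.71 ± 0.57 in controls and 8.27 ± 0.41 in cKO (1.56, SE 0.28, adjusted p = 0.58). Lama3, a laminin chain, was at 8.10 ± 1.02 and 6.07 ± 0.37 (adjusted p = 0.58), and the axon guidance protein Sema3d at 10.70 ± 1.09 and 8.13 ± 0.74 (adjusted p = 0.58). The Notch modifier Lfng (1.22, SE 0.29), Slc26a11 (1.58, SE 0.41), Calml4 (1.17, SE 0.31) and Aph1b (1.10, SE 0.28) were higher in cKO, and Rgs11 (-0.96, SE 0.21), the chloride cotransporter Slc12a2 (-1.46, SE 0.33) and Il10 (-0.73, SE 0.18) lower, each with adjusted p = 1.

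Among lists at 14 months, camera called ER stress (median 0.33) and senescence and secreted factors (0.17) up and cytosolic ribosomal proteins (-0.085) and skeletal muscle markers (-0.46) down, with 0 members past the test over all genes. Adjusted over the list alone, 1 gene of the senescence list passed, Igfbp5, and 0 of the others. With an estimated correlation all 4 calls were lost (adjusted p = 0.1, 0.281, 0.717 and 0.565 with an estimated correlation). Muscle markers lay a median of 1.48 above their means over all arrays on control array 4. Without it their median difference was -0.11 (adjusted p = 0.3). For the lists on the disc, 0 genes of collagens and fibrosis passed over all genes or adjusted over the list alone. Tgfb2 differed by 1.08 (SE 0.36, unadjusted p = 0.0077, limma) and Col1a1 by 0.47 (SE 0.21). The cartilage genes Ucma (1.45, SE 0.55), Vcan (-0.62, SE 0.24) and Prg4 (-0.85, SE 0.36), the hypoxia genes Bnip3 (0.63, SE 0.26), Car9 (0.86, SE 0.53) and Angptl4 (-0.34, SE 0.24), and the glycolytic gene Slc2a3 (-0.62, SE 0.41) did not pass either. Nor did the notochord genes Noto (-0.50, SE 0.29), Ncam1 (-0.47, SE 0.35) and Foxa1 (0.32, SE 0.25), or the catabolic genes Cxcl1 (0.28, SE 0.21), Adamts5 (0.35, SE 0.32) and Ptgs2 (0.42, SE 0.38). In simulated data, the same test recovered 51 of 100 genes changed by 1 and 92 of 100 changed by 2 (log2) at this age. Those data had independent noise and no sex imbalance, so recovery on the real arrays may differ.

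The genotype effect differed between the ages for 17 genes, 16 of which had a lower cKO-minus-control difference at 14 than at 6 months, though the count depended on single arrays, from 2 to 217 leaving out 1. Other groupings tried that kept the 6-month division but changed the 14-month labels gave more calls, up to 621. Nr4a1 differed by 3.92 at 6 months and -0.08 at 14 (difference of differences -4.00, SE 0.53, adjusted p = 0.0083), and Ifrd1 by 3.82 and 0.37 (-3.45, SE 0.47, adjusted p = 0.0083). The same held for Pim1 (-4.78, SE 0.86), Atf3 (-4.31, SE 0.70), Pde4b, a cyclic AMP phosphodiesterase (-3.80, SE 0.62), Gadd45g, a stress-response gene (-3.56, SE 0.57), Hk2 (-2.75, SE 0.49), Slc2a1 (-1.29, SE 0.24) and Egln1 (-1.51, SE 0.27). Sema3d (-4.20, SE 0.72) and Lama3 (-3.18, SE 0.56) had positive differences at 6 months (1.64 and 1.15) and negative ones at 14 (-2.57 and -2.03). For both genes the control and cKO arrays overlapped at 6 months. Their 14-month differences did not pass (limma adjusted p = 0.58), so a reversal of the genotype effect is not shown. Ndnf alone had the opposite sign (2.80, SE 0.52, adjusted p = 0.046), a call that was lost with every array shifted to one median (adjusted p = 0.08). Dbp (3.16, SE 0.64, adjusted p = 0.082), Adgrg6 (2.04, SE 0.41, adjusted p = 0.082) and Igfbp5 (1.88, SE 0.40) did not pass. After quantile normalization the split of calls was 3 higher and 14 lower, against 1 and 16, and the calls of Hk2, Slc2a1 and Egln1 were lost. Leaving out 1 array gave 217 calls without 6-month cKO array 1 and 2 to 10 without 6-month controls 1 (5) or 3 (2), 6-month cKO 3 (2) or 4 (2), 14-month controls 3 (10) or 4 (9), or 14-month cKO 1 (2), 2 (5), 3 (3) or 4 (5).

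Camera called 8 lists for this difference, all lower at 14 months. Glycolysis (median -0.96, 2 of 18 genes passing and 12 adjusted over the list alone) and immediate early and heat shock genes (-1.44, 3 of 17 and 5 adjusted over the list alone) held with an estimated correlation (adjusted p = 0.0345 and 0.0403). The other 6 did not: hypoxia genes (-0.78), ribosomal proteins (-1.02), oxidative phosphorylation (-0.34), autophagy (-0.26), neutrophil markers (-0.84) and muscle markers (-0.56), with adjusted p = 0.198, 0.198, 0.479, 0.507, 0.725 and 0.786 with an estimated correlation. Adjusted over the list alone, 8 hypoxia genes, 9 ribosomal protein genes and 1 autophagy gene passed, all lower, and 0 of the other 3 lists. The neutrophil call was lost without cKO arrays 3 and 4 of 6 months (median 0.34, adjusted p = 0.13), and the muscle call without 14-month control array 4 (median -0.18, adjusted p = 0.71). Of the 1035 probe sets called at 6 months, 774 (74.8%) had the same sign at 14 months, with a median change of 0.18 against 1.22. The calls were selected by their 6-month change, which makes that change look too large, so part of the drop may come from the selection. Sex was unevenly spread the same way at both ages, and off the Y chromosome 610 of 869 (70.2%) had the same sign, with a median of 0.13 against 1.15. With sex as a covariate that was 487 of 869, with a median of 0.042 against 1.02. Across all probe sets, which are not independent replicates, the genotype differences at the 2 ages had r = 0.422 and Spearman's rho = 0.211, and r = 0.264 with sex as a covariate.

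**Figure D3:**
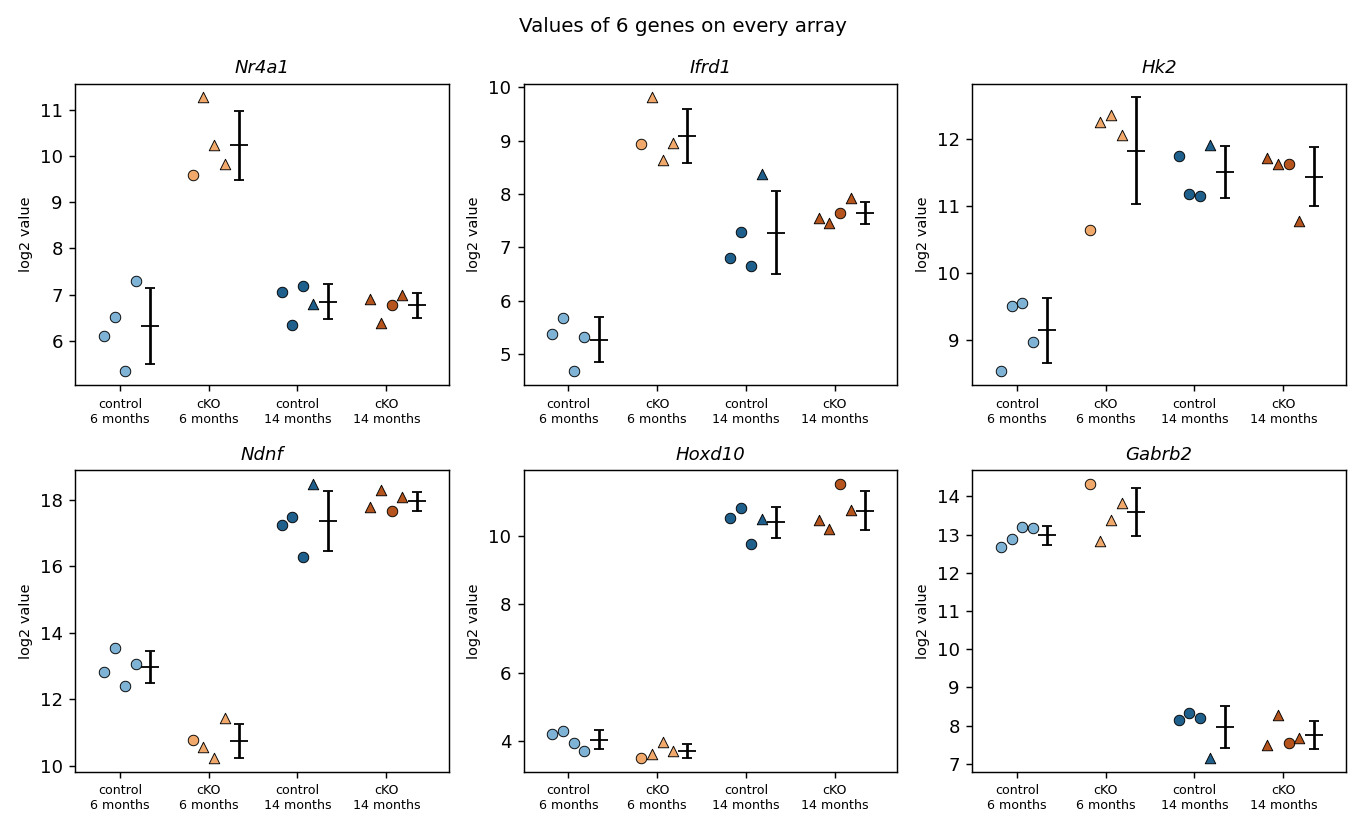
Log2 values of Nr4a1, Ifrd1, Hk2, Ndnf, Hoxd10 and Gabrb2 on each of the 16 arrays by group, with circles for arrays read as female, triangles for arrays read as male, and bars for the mean and SD of 4 arrays. Nr4a1 is at 10.23 in 6-month arrays labelled cKO against 6.31 in 6-month controls, and Hoxd10 is near 4 in both 6-month groups and above 10 in both 14-month groups.

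Between 6 and 14 months, transcripts of Hoxd10, Nrn1 and the cell cycle inhibitor Cdkn1a rose in control tissue, and those of Fgl2, Mt2 and Gabrb2 fell. Hoxd10, a homeobox gene of body axis position, rose 80.4-fold from 4.05 ± 0.26 to 10.38 ± 0.45 (6.33, SE 0.27, adjusted p = 1e-10, n = 4). Nrn1, a neurite growth protein, rose 140-fold (7.13, SE 0.58, adjusted p = 4.7e-07), the phospholipid transfer protein Pltp 38.3-fold (5.26, SE 0.34), Cdkn1a 33.2-fold (5.05, SE 0.45) and Ndnf 21.1-fold (4.40, SE 0.37). The protease inhibitor Serpina3n rose from 5.16 ± 0.32 to 13.42 ± 2.76, with the widest SE of the named rises (8.26, SE 1.97, adjusted p = 0.0039). The sorting receptor Sorl1 (5.24, SE 0.82) and the peptide hormone gene Adm (4.55, SE 0.95) rose as well. Fgl2, a fibrinogen-like protein, was 73.5-fold lower (-6.20, SE 0.57), the metallothionein Mt2 40.4-fold (-5.34, SE 0.65), the GABA receptor subunit Gabrb2 32.4-fold (-5.02, SE 0.31) and the DNA-binding inhibitor Id2 18.1-fold (-4.18, SE 0.45). The imprinted RNA Ipw (-4.92, SE 0.87), the glypican Gpc6 (-4.60, SE 0.73), Tmem176b (-4.54, SE 0.53) and Slc7a8 (-4.27, SE 0.59) fell too. On each of these genes the 4 arrays of 1 age did not overlap those of the other. Hoxd10 and Serpina3n at 6 months lay below the receptor probe sets (5.45), so their folds depend on the floor of the values.

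In the controls' ageing lists, oxidative phosphorylation changed most uniformly: 16 of 22 genes rose and 0 fell (17 adjusted over the list alone), among them Sdhb (1.81, SE 0.19) and Uqcrc1 (2.16, SE 0.27). Of 20 other hypoxia genes 10 rose and 0 fell (13 adjusted over the list alone), including Bnip3 (3.22, SE 0.26), Higd1a (3.65, SE 0.30) and Mxi1, a repressor of the Myc network (1.92, SE 0.30). Of 18 glycolytic genes 9 rose and 2 fell (9 and 3 adjusted over the list alone), Hk2 by 2.37 (SE 0.35) and Slc2a1 by 1.61 (SE 0.17). Of 16 autophagy genes 8 rose, such as Map1lc3a (1.77, SE 0.29), of 14 ER stress genes 8 rose, such as Dnajb9 (1.47, SE 0.22), and of 13 ribosomal protein genes 8 rose, such as Rpl27 (2.29, SE 0.27); adjusted over the list alone, 8, 8 and 9 rose. Of 10 HIF pathway genes 3 rose, Egln1 by 2.63 (SE 0.19), again 3 adjusted over the list alone. Of 11 lymphocyte markers 4 fell, Vpreb1 by 1.08 (SE 0.23), and of 9 erythroid markers 3 fell, Epb42 by 1.26 (SE 0.38); adjusted over the list alone, 4 and 6 fell.

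Camera called these 9 lists, and none of them held with an estimated correlation. The values were 0.209 for oxidative phosphorylation, hypoxia and ER stress, 0.313 for autophagy, the HIF pathway, lymphocyte and erythroid markers, and 0.419 for glycolysis and ribosomal proteins, each an adjusted p with an estimated correlation. After quantile normalization 2 of the calls remained, oxidative phosphorylation and the hypoxia genes. Genes of the matrix went both ways, as did all probe sets, of which 3732 of 22206 were called higher and 3846 lower. List counts near those shares say little about the list. Of 23 cartilage matrix genes 6 fell and 2 rose, the same counts adjusted over the list alone, 6 and 2: Hapln1, which links proteoglycan to hyaluronan, fell (-1.51, SE 0.24), as did Snorc (-2.06, SE 0.39) and Col2a1 (-1.17, SE 0.29), while the lubricating proteoglycan Prg4 rose by 1.62 (SE 0.36). Of 27 collagen and fibrosis genes 6 rose and 2 fell (5 and 2 adjusted over the list alone), with Col6a3 (1.60, SE 0.29), Col5a1 (1.77, SE 0.33) and Tgfb2 (1.69, SE 0.36) rising. Of 16 nucleus pulposus and notochord markers 4 rose and 3 fell (5 and 3 adjusted over the list alone), with Shh, a signalling protein of the notochord, at -1.70 (SE 0.26) and Krt18 at -1.81 (SE 0.35). The median of that list was -0.14, though camera's direction was up (adjusted p = 0.988). Of 19 small leucine-rich proteoglycan and elastic fibre genes 4 fell, Prelp by 1.75 (SE 0.26) and elastin (Eln) by 1.01 (SE 0.24), also 4 adjusted over the list alone. The proteases Ctsl (2.28, SE 0.39) and Mmp14 (1.63, SE 0.38) rose, and the chemokines Ccl2 (-1.10, SE 0.22) and Ccl5 (-0.99, SE 0.28) fell.

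In total 7578 probe sets were called in controls, 3732 higher and 3846 lower at 14 months (3444 and 3088 distinct named genes), 4014 of them over 2-fold. The median change of all probe sets was -0.10. With every array shifted to one median it was 0.095, and the split was 4872 higher and 2360 lower. Of the named falls of low genes, those of Cd79b, Cd3e, Epb42, Ccl7 and Ptprc lost their call after quantile normalization. The Btbd35f family of multi-copy germline genes had a median change of -3.11 and 1414 receptor probe sets one of -0.67, and whether what lowers them also moved other genes was not tested. The labels give no hybridisation batch, so a batch that followed age cannot be told apart from age.

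In arrays labelled cKO, many of the same genes were higher at 14 than at 6 months. Hoxd10 rose 129-fold from 3.71 ± 0.20 to 10.72 ± 0.57 (7.01, SE 0.27, adjusted p = 1.7e-11, n = 4), Nrn1 162-fold (7.34, SE 0.58), Ndnf 147-fold (7.20, SE 0.37), Hoxd9 26.1-fold (4.71, SE 0.35) and Hoxd8 19.6-fold (4.29, SE 0.22). The cholesterol exporter Abca1 rose 33.9-fold (5.08, SE 0.36), the lysosomal mannosidase Man2b1 32.8-fold (5.04, SE 1.06) and the lipopolysaccharide-binding protein Lbp 25.2-fold (4.66, SE 0.48). Sema3d fell 108-fold, from 14.89 ± 0.92 to 8.13 ± 0.74 (-6.75, SE 0.51, adjusted p = 2.1e-07), Mt2 79.2-fold (-6.31, SE 0.65), Gabrb2 57.3-fold (-5.84, SE 0.31) and Fgl2 51.3-fold (-5.68, SE 0.57). The osmolyte transporter Slc6a12 (-5.25, SE 0.38), Tmem176b (-5.11, SE 0.53) and the chemokine Cxcl12 (-4.99, SE 0.67) fell, as did the neutrophil granule protein Ngp (-5.37, SE 1.23), which was at 9.57 ± 4.00 at 6 months. Hoxd10 (3.71) and Hoxd9 (4.25) at 6 months lay below the receptor probe sets (5.23), as did Ngp (4.20) at 14 months (4.71), so these folds depend on the floor too.

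Of 17 immediate early and heat shock genes 12 fell and 0 rose in cKO (13 fell and 1 rose adjusted over the list alone), including Nr4a1 (-3.46, SE 0.37), Atf3 (-3.86, SE 0.49), Dusp1 (-4.36, SE 0.80) and Hsph1 (-2.13, SE 0.30). Of 22 oxidative phosphorylation genes 9 rose (13 adjusted over the list alone), Sdhb by 1.93 (SE 0.19). Of 20 hypoxia genes 6 rose and 1 fell (9 and 2 adjusted over the list alone): Bnip3 (1.90, SE 0.26), Higd1a (2.11, SE 0.30) and the transcriptional co-regulator Cited2 (2.25, SE 0.38) rose and Angptl4 (-1.37, SE 0.24) fell. Of 16 autophagy genes 8 rose, Lamp2 by 0.86 (SE 0.19), and of 14 ER stress genes 5 rose, Hsp90b1 by 1.03 (SE 0.17); adjusted over the list alone, 8 rose and 1 fell, and 5 rose. Of 16 inflammation and NF-kB genes 5 fell (6 adjusted over the list alone), Ptgs2 by 1.62 (SE 0.38) and Icam1 by 0.82 (SE 0.21). Of 14 neutrophil markers 9 fell, S100a8 among them (-4.93, SE 1.23), and of 15 macrophage markers 4 fell, with Lyz2 at -3.01 (SE 0.81), the same counts adjusted over the list alone, 9 and 4. Both of these calls were lost without 6-month cKO arrays 3 and 4 (adjusted p = 0.18 and 0.76), and so was that of ER stress (adjusted p = 0.054). Camera called these 8 lists, and none held with an estimated correlation (adjusted p = 0.231 for inflammation, 0.265 for the immediate early and oxidative phosphorylation lists, 0.314 for ER stress and 0.377 for the other 4, all with an estimated correlation).

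Glycolytic genes fell in 6 of 18 cases and rose in 0 in cKO (6 and 1 adjusted over the list alone), with Slc2a3 at -3.40 (SE 0.41), Pfkl at -2.31 (SE 0.34) and Pfkp at -1.40 (SE 0.25), though camera did not call the list (adjusted p = 0.0679). Over all probe sets, 2818 of 22206 were called higher and 2257 lower in cKO, and list counts near those shares say little about the list. Of 23 cartilage matrix genes 2 fell and 2 rose (2 and 1 adjusted over the list alone), with Snorc at -3.33 (SE 0.39) and Hapln1 at -1.66 (SE 0.24). Of 27 collagen and fibrosis genes 8 rose and 3 fell (8 and 4 adjusted over the list alone), with Col6a3 (1.60, SE 0.29), Col5a1 (1.76, SE 0.33), Col1a1 (1.04, SE 0.21) and Sparc (0.96, SE 0.21) rising. The list's median was -0.22, its mean 0.014 and camera's direction up (adjusted p = 0.77). Of 16 nucleus pulposus and notochord markers 4 fell and 2 rose, the same counts adjusted over the list alone, 4 and 2, with Krt18 at -3.72 (SE 0.35) and Shh at -1.99 (SE 0.26); the median was 0.12, the mean -0.33 and camera's direction down (adjusted p = 0.646). Igfbp5 (2.95, SE 0.28) and Cdkn1a (2.96, SE 0.45) of the senescence list, the proteases Adamts1 (2.77, SE 0.53) and Mmp14 (1.81, SE 0.38) and the osteoclast regulator Nfatc1 (1.97, SE 0.26) rose.

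Limma called 5075 probe sets with age in cKO, 2818 higher and 2257 lower (2590 and 1715 distinct named genes), 2861 of them over 2-fold. The median change of all probe sets was -0.075, and 0.055 with every array shifted to one median, where the split was 3450 higher and 1619 lower. The age effects in the 2 genotypes, which share no arrays, had r = 0.771 and Spearman's rho = 0.751 across probe sets. Of the calls, 2062 were higher in both and 1493 lower in both, where independent lists of these sizes would share 473.6 and 390.9, and 16 went in opposite directions. A batch or a difference in the RNA that followed age would move both genotypes alike. The overlap therefore does not single out age as the cause. Male and female arrays were 3 and 1 in both cKO groups, and the male arrays alone gave 4117 calls, 3570 of them shared with the 5075. The female arrays alone, 1 at each age with the spread taken from the other groups, gave 296. Without 14-month cKO array 3, 3366 were called.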

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

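The tests of sex and of the clock at 6 months, the tests on Hox genes and the counts of shifted lists under other groupings of the arrays were chosen only after the result was seen. Several were also changed after a first form had been run, and the first values are given beside the later ones. A further explanation of the 6-month difference, by the spread of values between arrays, was dropped after results were seen, and quantile normalization gave 1099 calls there against 1035.

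Of 220 sets of 4 arrays, 10 held 1 array far from the other 3, where chance gives about 1 in 20. Among 6-month arrays, Hif1a was at 13.04 on cKO array 1 (others 14.38 to 14.45), 1 probe set of Sly at 7.85 on the same array (others 12.74 to 13.68), Mt2 at 15.81 on cKO array 3 (others 17.76 to 17.95) and Atf7ip at 9.23 on control array 3 (others 9.87 to 9.96). Among 14-month arrays, Aph1b was at 9.05 (others 7.44 to 7.66) and Slc12a2 at 16.27 (others 17.98 to 18.18) on control array 1, Hoxd9 at 7.92 on control array 2 (others 8.77 to 8.91), and Gabrb2 at 7.15 (others 8.15 to 8.34) and Gadd45g at 8.56 (others 6.67 to 6.80) on control array 4. Slc12a2 was also at 15.74 on cKO array 2 (others 16.32 to 16.37). The cKO array with low Sly was the female one of its group.

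The difference between cKO and control changed with age, by limma's test of that difference, for 17 genes. It was lower at 14 than at 6 months for Pim1 (-4.78), Atf3 (-4.31), Sema3d (-4.20), Nr4a1 (-4.00), Pde4b (-3.80), Gadd45g (-3.56), Ifrd1 (-3.45), Lama3 (-3.18), Klf10 (-2.86), Hk2 (-2.75), Tuba4a (-2.66), Hspa1a (-2.07), Fam162a (-1.99), Klhl21 (-1.67), Egln1 (-1.51) and Slc2a1 (-1.29), and higher for Ndnf (2.80). Of these, 15 were also called at 6 months. Camera called 8 lists, with medians of -1.44 for immediate early and heat shock genes, -1.02 for ribosomal proteins, -0.959 for glycolysis, -0.836 for neutrophil markers, -0.784 for other hypoxia genes, -0.558 for muscle markers, -0.344 for oxidative phosphorylation and -0.255 for autophagy. The immediate early and glycolysis lists held with an estimated correlation (adjusted p = 0.0403 and 0.0345), and the other 6 did not (adjusted p = 0.198 to 0.786 with an estimated correlation).

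The first pattern is the difference between arrays labelled cKO and control at 6 months, where genotype and sex overlap. Over the Y-linked called probe sets, the only female cKO array differed from the controls by a median of 0.014 and the male ones by 5.46, so this part goes with sex. For the other 869, the male minus female difference at 14 months was signed by the 6-month change. Its median was 0.162 (-0.033 to 0.347 leaving out 1 array) against a change of 1.15, which argues against a sex effect that is the same at both ages. The 1.15 comes from the arrays that selected the calls and may be too large. The first form of this test, over all calls, gave 0.22 (0.037 to 0.38). On the Y-linked calls, which go with sex, the same test gave 1.68 (0.65 to 2.55) against 4.09. A sex effect that is weaker at 14 months therefore stays open. The 869 also hold X-linked probe sets: 266 calls had an X or Y identifier, against 166 with Y. A sex effect present at 6 months only cannot be told apart from genotype, since 1 array carries the test: on autosomal probe sets called from male arrays the female cKO array moved by 0.66 (0.50 to 0.83 over 6 divisions of the controls), the male ones by 1.24 and held-out controls by 0.31. A difference in clock phase also stays open. Opposite-phase genes exceeded those in phase with Dbp by 1.02 (exact permutation p = 0.079, 165 arrangements) over the 11 genes whose values had not prompted the test. In its first form, over all 14, the difference was 1.75 (exact permutation p = 0.03). These 2 p-values come from exchanging genes, which are not independent replicates, and do not measure the spread between arrays. The genotype itself, and the DNA weighed in the next paragraph, stay open as untested explanations.

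The second pattern is that multi-copy germline genes were high at 6 months: all 23 Btbd35f probe sets were called lower at 14 months in controls (median -3.11) and 17 in cKO. Quantile normalization left the median in controls at -3.40, which argues against a difference in the spread of values, and among female controls it was -2.27, which argues against sex as the whole cause. Genomic DNA carried over into the RNA of the 6-month arrays may explain it. Over 212 Y-linked probe sets outside the broadly expressed Y genes, male arrays were higher at 6 months (n = 3) than at 14 (n = 4) by a median of 3.08, and female arrays, which lack that DNA, by 0.039. These probe sets were taken as multi-copy without a check of copy number. The male 6-month arrays were all cKO, with medians of 9.74 to 11.4. Male 14-month arrays had 7.65 to 8.09 in cKO and 6.24 on the control. The 6-month groups also differed, with a median of -1.85 for Btbd35f between cKO and control (5 probe sets called lower) and -0.24 for receptor genes. Of 4 arrays each, 0 control and 3 cKO arrays were male, so sex cannot be told apart from unequal DNA here. The Btbd35f median was 9.3 on the female cKO array, 10.3 to 11.3 on the controls and 7.8 to 9.48 on the male cKO arrays. Unequal DNA thus stays open for part of the 6-month difference and of the age differences of other genes. Neither transcription of these genes nor the shift such DNA would give other genes was tested.

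The third pattern is the rise of Hox genes of paralog groups 8 to 11 with age, in 5 of 12 measured, over 2-fold in both genotypes. Annulus and tendon cells in the 14-month tissue cannot be told apart from age: their 8 of 14 markers that were low at 6 months had a median change of 0.078 (first form, over all 14, -0.27), but 5 of the 8 lay below the receptor probe sets, whose own median fell by 0.67, so the bound set for this test does not exclude such cells. Sex is argued against by the change among female controls, a median of 4.22 against 4.18 over all controls; a first form used Hoxd10 alone (6.30 against 6.33). A different disc level at the 2 ages could give such a rise and cannot be told apart from age, since 1 of the 6 genes of these groups in the b and c clusters lay above the array median at either age, which leaves too few to test. In the first form of that test, 2 of 4 clusters held a raised gene of groups 9 to 11, and age itself stays open.

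Other groupings of the same arrays show where the real one gave the most. For called probe sets it did at 6 months (1035, highest other 335, 1 of 35 groupings as large), for age in controls (7578, highest other 28, 1 of 35) and for age in cKO (5075, highest other 189, 1 of 35). A share of 1 of 35 is the smallest that so few groupings can give, so chance is not excluded. At 6 months the real grouping also divides most males from females, so its rank does not speak for genotype alone. At 14 months the count was 0 by limma (795 at an unadjusted p under 0.05; highest other 8), so all 35 of 35 groupings are as large by construction and say nothing about chance. For genotype by age (17, highest other 621, 6 of 100 as large), the 6 were those that kept the real division of the 6-month arrays, and the other 94 gave 0 or 1. Among those 6, which gave 17 to 621 calls, the real grouping gave the fewest. The 17 calls are thus not shown to depend on the real 14-month labels. These groupings thus show a structure of the samples, that 6-month division, and do not test the term itself against chance. For shifted lists chance cannot be excluded in any comparison: 9 at 6 months (highest other 11, 4 of 35), 4 at 14 months (highest other 4, 3 of 35), 9 for age in controls (highest other 11, 4 of 35), 8 for age in cKO (highest other 8, 3 of 35) and 8 for genotype by age (highest other 13, 21 of 100, 15 of them among the 94 above).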

How the results depend on the processing

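Arrays of 1 sex only, the omission of 6-month cKO arrays 3 and 4 and the sex covariate for the correlations and for the signs of the 6-month calls at 14 months were chosen after seeing the data. The cause of the changes below was not tested, beyond fewer arrays or another threshold where a setting is built that way. The count of 1035 probe sets at 6 months was 324 with only the arrays of the 2 groups, 1821 at an adjusted p under 0.10, 61 with sex as a covariate, 52 on female arrays (1 of them cKO, assumed to vary like the other groups), and 92 without cKO arrays 3 and 4. Leaving out 1 array gave 288 to 1259: 508, 288 and 535 without control arrays 1, 3 and 4, and 382 and 314 without cKO arrays 3 and 4. Its 9 lists became 3 with an estimated correlation, and 8 to 10 leaving out 1 array. At 14 months limma called 0, with 795 at an unadjusted p under 0.05: 121 of these passed an unadjusted p under 0.05 and 2-fold, 1 passed with the sex covariate, 2 on female arrays (1 of them cKO) and 7 on male arrays (1 of them control), where the lone array is assumed to vary like the other groups, and 0 to 4 leaving out 1 array (4 without control array 1). The 4 lists became 0 with an estimated correlation, 0 with fry, 1 on female and 1 on male arrays, and 1 to 5 leaving out 1 array (1 without control array 4, 2 without cKO array 1 and 2 without cKO array 2). For age in controls, 7578 became 4082 at an unadjusted p under 0.05 and 2-fold. Its 9 lists became 2 after quantile normalization, 2 without dim probe sets, 0 with an estimated correlation and 15 with fry. For age in cKO, 5075 became 3080 at the same unadjusted threshold and 296 on female arrays, and leaving out 1 array gave 3366 (without 14-month cKO array 3) to 5532. Its 8 lists became 5 after quantile normalization, 5 without dim probe sets, 0 with an estimated correlation and 19 with fry. For genotype by age, 17 became 43 with array weights, 52 at an adjusted p under 0.10, 895 at the unadjusted threshold and 3 without 6-month cKO arrays 3 and 4. Leaving out 1 array gave 2 to 217: 217 without 6-month cKO array 1; 2 without 6-month control 3, 6-month cKO 3, 6-month cKO 4 or 14-month cKO 1; 3 without 14-month cKO 3; 5 without 6-month control 1, 14-month cKO 2 or 14-month cKO 4; and 10 and 9 without 14-month controls 3 and 4. Its 8 lists became 5 without dim probe sets, 2 with an estimated correlation, 3 with fry and 5 without 6-month cKO arrays 3 and 4, and 5 to 8 leaving out 1 array (5 without 6-month cKO array 4 or 14-month cKO array 3). The correlation of genotype effects (0.422) was 0.471 without dim probe sets, 0.264 with the sex covariate and 0.283 to 0.523 leaving out 1 array. That of age effects (0.771) was 0.785 without dim probe sets, 0.737 after quantile normalization, 0.796 with the sex covariate and 0.725 to 0.790 leaving out 1 array. Among named values, the sign of 1 call reversed: Chst11 with age in cKO, 0.07 on female arrays against -0.91.

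With the replicate number as a block the counts of probe sets were 928 (854 of them shared with the 1035), 0 (limma), 7316, 4826 and 15, and those of lists 10, 4, 9, 8 and 8, in the order of the comparisons above. The numbers do not pair the arrays: of 24 pairs with the same number 3 had r over 0.1 (-0.28 to 0.27), and 5 of 16 arrays matched their own number best. Signal over background is not given in the sources used here, so what it limits was not measured.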

Other observations

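Of 15 measured Hox genes of the a and d clusters, 7 rose with age in both genotypes (6 after quantile normalization and 7 with arrays shifted to one median). Hoxa10 rose by 3.47 (SE 0.32) in controls and 3.93 (SE 0.32) in cKO, Hoxd11 by 1.83 (SE 0.33) and 2.98 (SE 0.33), and Hoxa6 by 1.07 (SE 0.26) in controls. Of 33 measured Hox genes, 1 of 15 in paralog groups 1 to 7 and 0 of 6 in groups 12 and 13 rose over 2-fold in both genotypes. These genes were chosen after their values were seen. Clock genes moved with age as well: in controls 5 of 16 rose and 5 fell, with Cry2 at 1.90 and Nr1d1 at -1.56, and in cKO 4 rose and 4 fell, with Per3 at 3.00 and Npas2 at -3.65.

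Olfactory and vomeronasal receptor probe sets, 1414 in number, had a median change of -0.67 with age in controls and -0.51 in cKO, and of -0.24 and -0.085 between cKO and control at 6 and 14 months. The Btbd35f probe sets had a median of -0.995 between cKO and control at 14 months, where 3 of 4 cKO and 1 of 4 control arrays were male.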
